A study of Homo sapiens with 6 samples.

How the data were processed

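Total RNA of LM2-4175 cells was labelled with biotin after cDNA synthesis and hybridised to 6 Affymetrix 3' expression arrays, 3 for control cells and 3 for cells labelled as stably over-expressing KLF4, per the labels' protocols. The authors deposited 1 table of log2 expression values, 1 column per array and 1 row per probe set, made with RMA per the submitters' processing notes, which give no version. RMA corrects background, quantile-normalizes the arrays and summarises the probes of a probe set on the log2 scale, so differences in overall signal between arrays are removed and small fold changes are compressed for dim probe sets. The log2 scale was checked on the values, which lay between 1.54 and 14.4 over the probe sets that are not controls. The deposited values carry no detection calls, and no genome build is given in the sources used here, so no coordinates are printed.

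The table held 54675 probe sets, of which 62 are array controls. Gene names came from GEO's platform annotation, with 41091 probe sets naming 1 gene symbol, 1801 naming several and 11721 unnamed here. Of those with 1 symbol, 41037 were found by gene ID in a table of RefSeq genes (assembly GRCh38.p14, used only for names), and 0 symbols needed updating. Probe sets with several symbols or none stayed out of the gene test. A gene was represented by its probe set with the highest mean over all 6 arrays, which gave 19775 genes, 10523 of them with more than 1 probe set. No filter on level was applied.

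The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, constant prior, two-sided, Benjamini-Hochberg over all genes), with a threshold of 0.05 on the adjusted p. The fit had 4 residual degrees of freedom and a prior worth 4.14, and the median residual SD was 0.10 on the log2 scale. Values are group means ± SD of log2 expression over 3 arrays, and fold changes are powers of 2 of the difference of the means. Gene lists (32, from textbook knowledge) were tested with limma's camera and a preset inter-gene correlation of 0.01, Benjamini-Hochberg over the lists, beside the same test with the correlation estimated per list and beside counts of members adjusted over the list alone. List genes without a probe set of their own symbol alone were not analysed here. Plots were drawn with matplotlib 3.10.9.

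The groups, the test, the lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule names KLF4, and the 12 genes with the largest positive and the 12 with the largest negative log2 difference among genes past the threshold whose groups do not overlap, leaving out symbols that start with LOC, LINC or MIR or contain orf or -AS. It also names up to 4 members past the threshold per list or, where none pass, the 1 with the smallest p, the 2 brightest markers of blood, endothelial cells and fibroblasts, and the control probe sets of ACTB and GAPDH. Alternatives were 3 between-array scalings, 2 filters on dim genes, 3 other choices of probe set, a robust level-dependent prior, array weights, an ordinary t statistic, the replicate number as a block, leaving out each array, 2 other list tests and a test against a 1.5-fold change. The arrays were compared in pairs before averaging, and none was a copy of another.

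The gene test was tested on simulated data with the means and spread of these 19775 genes. It recovered 52 of 67 genes changed by 0.5 on the log2 scale, 66 of 67 changed by 0.75 and 66 of 66 changed by 1, with 10 false calls and 0 calls of the wrong sign. A simulated shift of 0.15 in 1 list was found, with 0 of the other lists called.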

Results

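The study profiled mRNA in LM2-4175 cells, a derivative of the human MDA-MB-231 breast cancer line that was selected for spreading to the lung. One group of 3 arrays came from control cells and the other group of 3 arrays from cells that the labels describe as stably over-expressing KLF4 from a lentiviral plasmid. KLF4 is a zinc-finger transcription factor of the Krüppel-like family. Each array was an Affymetrix 3' expression array, on which a probe set is a group of short probes read as 1 value, and the values are log2 RMA expression. The array medians over the probe sets that are not controls lay between 4.92 and 4.96, and the correlation across probe sets between any 2 arrays lay between 0.9956 and 0.9971, where probe sets are not independent replicates. The highest correlation joined 2 arrays of different groups, control replicate 1 and KLF4-labelled replicate 2. Nothing in the labels says that the 3 samples of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision, and the median standard error of a gene's log2 difference was 0.08.

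The series asks which transcripts KLF4 regulates in breast cancer cells, and the level of KLF4 itself checks the labels. KLF4 was measured lower, not higher, on the arrays labelled KLF4 over-expression. On probe set 221841_s_at the log2 expression was 8.47 ± 0.07 (SD, n = 3) in control and 8.10 ± 0.09 (SD, n = 3) on the KLF4-labelled arrays. This is a 1.29-fold lower signal, with a log2 difference of -0.37 (95% interval -0.54 to -0.20) and a limma adjusted p of 0.103, above the threshold of 0.05. On the dimmer probe set 220266_s_at the values were 6.41 ± 0.07 and 6.18 ± 0.08 (SD, n = 3 each), a difference of -0.23 (95% interval -0.41 to -0.05). On both probe sets all 3 KLF4-labelled arrays lay below all 3 control arrays. The KLF4 difference stayed negative and passed the threshold with a filter on dim genes or a robust, level-dependent prior, with adjusted p values of 0.0320, 0.0156 and 0.0118. The positions of these probes on the KLF4 transcript, and the part of KLF4 carried by the plasmid, are not given in the sources used here. The arrays are therefore called KLF4-labelled below, and every direction is that of the KLF4-labelled arrays relative to the control arrays.

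**Figure D1:**
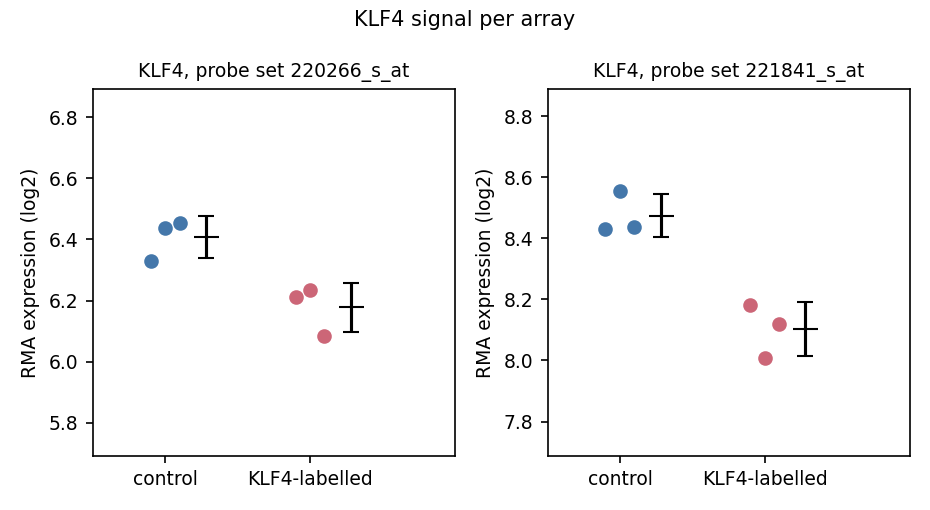
RMA expression (log2) of KLF4 on its 2 probe sets, with 1 point per array, and a bar at the group mean with the SD (n = 3). On both probe sets the 3 KLF4-labelled arrays lie below the 3 control arrays, with mean differences of -0.23 and -0.37.

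The comparison of the groups asked which other genes differed. The strongest rises on the KLF4-labelled arrays were in the MHC class II genes HLA-DRA, HLA-DPB1 and HLA-DPA1, which present antigen to helper T cells, and in VCAM1, an adhesion molecule that binds leukocyte integrins. HLA-DRA went from 7.90 ± 0.10 to 9.08 ± 0.10 (SD, n = 3 each), a 2.27-fold rise. VCAM1 went from 7.60 ± 0.14 to 8.76 ± 0.04, a 2.24-fold rise. The strongest falls were in ESM1, a proteoglycan secreted by endothelial and tumour cells, from 5.87 ± 0.07 to 4.69 ± 0.06, in KRABD1 (2.13-fold lower) and in LAMB1, a laminin chain of basement membranes, from 8.11 ± 0.02 to 7.14 ± 0.09 (1.96-fold lower).

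Of 19775 genes tested with limma, 76 changed at an adjusted p under 0.05, of which 51 rose and 25 fell (67.1% higher). All 76 had 3 KLF4-labelled arrays on the same side of all 3 control arrays, a separation that 19.1% of all genes showed and that chance gives for 10%. The changes were small, since 99.4% of genes differed by less than 0.5 on the log2 scale, 37 of the 76 changed by at least 1.5-fold and 6 by at least 2-fold (4 higher and 2 lower). Leaving out 1 array reduced the count of changed genes to 13 (control replicate 1), 13 (control replicate 2), 19 (control replicate 3), 16 (KLF4-labelled replicate 1), 26 (KLF4-labelled replicate 2) and 13 (KLF4-labelled replicate 3). All 76 genes kept their direction in each of these 6 fits. That was fixed beforehand, since groups that do not overlap stay apart without any 1 array. Other settings gave between 0 genes (an ordinary t statistic without shared variance, with 2329 genes at an unadjusted p under 0.05) and 489 genes (a robust, level-dependent prior), against 2483 genes at an unadjusted p under 0.05 in the main fit.

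The other genes of the 12 largest rises came from several functions. COL15A1, a collagen of basement membrane zones, went from a dim 4.89 ± 0.10 to 5.77 ± 0.03. SCD, which desaturates fatty acids, rose 1.70-fold from 8.58 ± 0.07 to 9.35 ± 0.06. FGF13, an intracellular member of the fibroblast growth factor family, rose 1.69-fold from 9.44 ± 0.05 to 10.20 ± 0.0036. PTGES, the inducible prostaglandin E synthase, rose 1.68-fold on its brighter probe set and 1.74-fold on the other. ASB2, a substrate receptor of a ubiquitin ligase, rose 1.66-fold, and CCR1, a chemokine receptor, rose 1.62-fold. The remaining genes of this group were HLA-DRB1 (1.75-fold) and HLA-DMB (1.60-fold), and the adjusted p of the 12 lay between 0.00266 and 0.0340.

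Among the 12 largest falls were 3 genes of the MAGE family of cancer-testis antigens, MAGEB2 (1.94-fold lower), MAGEA6 (1.76-fold lower) and MAGEC2 (1.60-fold lower on its brighter probe set, with a log2 difference of -0.05 on the other). Near-identical family members can share probes, so the identity of the MAGE genes and of the HLA genes is uncertain. This holds most of all for MAGEA6 and HLA-DRB1, read only by probe sets whose names end in _x_at, and for HLA-DMA, read only by an _s_at probe set. ESM1 is also read only by an _x_at probe set, and VCAM1, FGF13, PTGES, CYP1B1, TOX, TIMP3 and DDIT4 only by _s_at probe sets. SCD is read only by probe sets with these 2 endings. KRT7, a keratin of simple epithelia, fell 1.74-fold on its brightest probe set, from 9.56 ± 0.07 to 8.76 ± 0.03, but its 4 probe sets ranged from -0.80 to 0.05 on the log2 scale and disagreed in sign. The dimmer ones differed by 0.05 ± 0.13, 0.02 ± 0.12 and -0.26 ± 0.20 (SE), at control levels of 6.57, 2.91 and 4.86. SLC7A11, the cystine transporter, fell 1.58-fold and CYP1B1, an oestrogen- and xenobiotic-metabolizing enzyme, 1.64-fold, with all of their 3 and 4 probe sets lower. The last 3 genes are dim, and for them, ESM1 and COL15A1 the values do not show a level above background in both groups. EPB41L3, a membrane skeleton protein, went from 4.43 ± 0.16 to 3.70 ± 0.10 with its 3 probe sets lower. TOX, an HMG-box nuclear factor, went from 5.61 ± 0.18 to 4.89 ± 0.05, with a log2 difference of -0.15 on its other, dimmer probe set. BMPR1B, a receptor of bone morphogenetic proteins, went from 5.47 ± 0.08 to 4.82 ± 0.08, and its other probe sets differed by -0.55 and -0.11. The adjusted p of these 12 falls lay between 0.00266 and 0.0491.

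**Figure D2:**
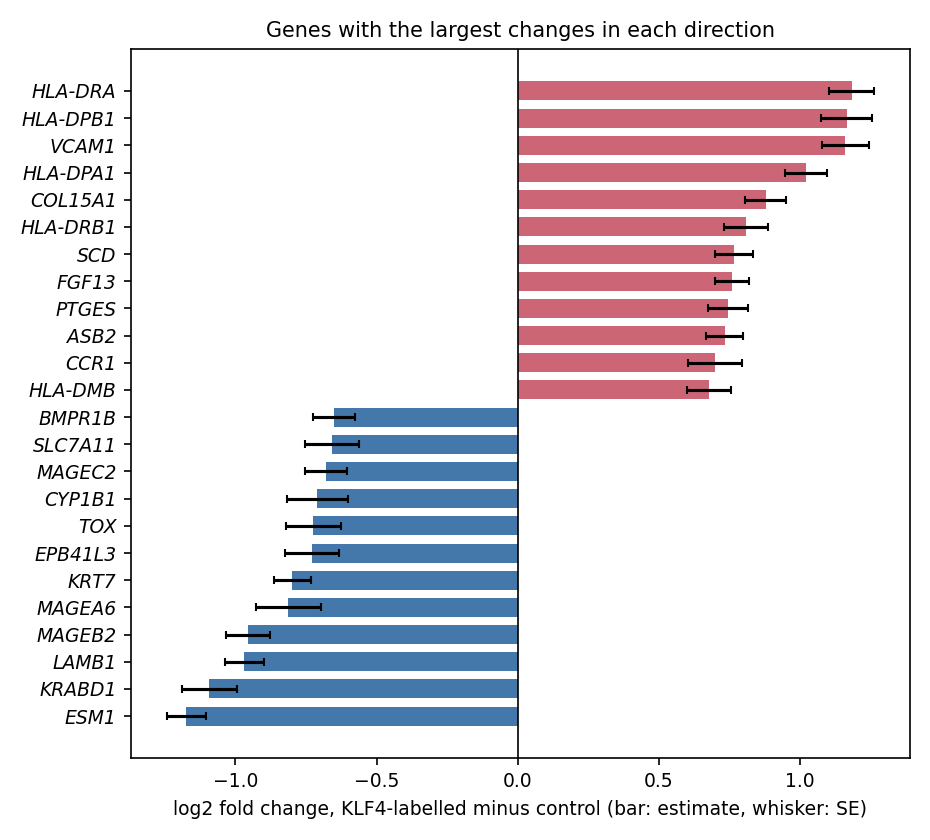
Log2 fold change (KLF4-labelled minus control) of the 12 genes with the largest rise and the 12 with the largest fall among the genes past the limma threshold, with the standard error as whisker (n = 3 arrays per group). The values run from 1.18 for HLA-DRA to -1.17 for ESM1.

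Of 32 gene lists, 6 shifted relative to all other genes in limma's camera test with a preset correlation of 0.01, and none did with an estimated correlation. The count of shifted lists was 11 without KLF4-labelled replicate 2 and 10 with array weights. The clearest was the antigen presentation list, in which 6 of 25 measured genes rose, all of them MHC class II genes (HLA-DRA, HLA-DPB1, HLA-DPA1, HLA-DRB1, HLA-DMB and HLA-DMA, the last 1.51-fold), and none fell. Adjusted over the list alone, 14 members rose, and 23 of the 25 had a positive difference. The list's median log2 difference was 0.26 and its camera adjusted p 1.25e-16 (adjusted p = 0.254 with an estimated correlation). In the interferon response list, OAS1, a sensor enzyme for double-stranded RNA, was higher at a dim level (4.25 ± 0.11 to 4.81 ± 0.02), as 1 of 48 genes (6 rose and 1 fell adjusted over the list alone), and the list itself did not pass (camera adjusted p = 0.0635). Beside these immune genes, the haematopoietic markers did not pass as a list (camera adjusted p = 0.711), with 0 of 19 markers past limma's threshold (0 adjusted over the list alone, 4 at an unadjusted p under 0.05). The 2 brightest of them differed by 0.27 (LAPTM5, control level 10.59) and 0.19 (LCP1, control level 10.51) on the log2 scale and did not pass. In the inflammatory cytokine and NF-kB list, CSF3, the granulocyte colony-stimulating factor, rose 1.43-fold from 10.65 ± 0.06 to 11.17 ± 0.01 as the only 1 of 32 genes past the threshold. Adjusted over the list alone 7 of its genes rose, and 23 of 32 differences were positive (camera adjusted p = 0.00375; adjusted p = 0.507 with an estimated correlation).

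Among lipid and energy genes, the cholesterol synthesis and uptake list was higher on the KLF4-labelled arrays, with 21 of 25 differences positive and a median of 0.09 (camera adjusted p = 7.57e-05; adjusted p = 0.507 with an estimated correlation). Its 1 member past the threshold was SCD, a fatty acid enzyme and not an enzyme of the cholesterol pathway, and 3 members rose adjusted over the list alone. The oxidative phosphorylation list was also higher, by a median of 0.05 with 36 of 43 differences positive and 0 genes past limma's threshold, also adjusted over the list alone, and 1 at an unadjusted p under 0.05 (camera adjusted p = 0.0407; adjusted p = 0.808 with an estimated correlation). Its member with the smallest p, COX4I1, differed by 0.16 ± 0.07 (SE, n = 3 per group). This call was lost under all 3 other scalings, both filters on dim genes, the probe set of largest SD, without probe sets marked _x_at or _s_at, with the replicate block and in the directional fry test. It was also lost in 5 of the 6 fits that left out 1 array, all but the one without KLF4-labelled replicate 2. The adjusted p values in these fits and settings were 0.0501 to 0.335. In the hypoxia and glycolysis list, DDIT4, an mTOR inhibitor induced by stress, rose 1.43-fold and ALDOC, a glycolytic aldolase, 1.41-fold, 2 of 38 genes (6 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.0754). The unfolded protein and ATF4 list held 1 gene that rose, DDIT4, and 1 that fell, SLC7A11, of 40 (2 and 2 adjusted over the list alone; camera adjusted p = 0.676). In the NRF2 and oxidative stress list SLC7A11 was the 1 of 34 genes past the threshold, 2 rose and 2 fell adjusted over the list alone, and 26 differences were positive (camera adjusted p = 0.0635).

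Growth-related lists moved little. The mitosis list was lower, with 38 of 50 differences negative and a median of -0.05 (camera adjusted p = 0.00375; adjusted p = 0.507 with an estimated correlation), and 0 of its genes passed limma's threshold, over all genes or adjusted over the list alone, with 8 at an unadjusted p under 0.05. Its member with the smallest p, the spindle gene ASPM, differed by -0.31 ± 0.07 (SE, n = 3 per group). The YAP and TEAD target list was lower too, with 16 of 23 differences negative, a median of -0.10 and 0 genes past the threshold in either adjustment, 5 at an unadjusted p under 0.05 (camera adjusted p = 0.00290; adjusted p = 0.254 with an estimated correlation), and CRIM1 in it differed by -0.29 ± 0.07 (SE, n = 3 per group). The mitosis call was lost without the probe sets marked _x_at or _s_at (camera adjusted p = 0.0981) and in the directional fry test (0.127). No call was made for DNA replication and S phase (0 of 46 genes in either adjustment, 8 at an unadjusted p under 0.05, camera adjusted p = 0.178, GINS2 at 0.27). The cell cycle inhibitor and p53 target list had 0 of 31 genes past the threshold (8 at an unadjusted p under 0.05) and 3 higher adjusted over the list alone (camera adjusted p = 0.731), with the p21 gene CDKN1A at a log2 difference of 0.34 (adjusted p = 0.0785). In the apoptosis list BCL2A1, an anti-apoptotic BCL2 relative, fell 1.38-fold as 1 of 30 genes in either adjustment (camera adjusted p = 0.638). The growth factor and receptor list had 0 of 45 genes past the threshold (11 at an unadjusted p under 0.05) and 1 higher adjusted over the list alone (camera adjusted p = 0.481), with VEGFA at 0.47 (adjusted p = 0.0824). The immediate early and heat shock list had 0 of 35 past the threshold (7 at an unadjusted p under 0.05) and 1 lower adjusted over the list alone (camera adjusted p = 0.218), with EGR1 at -0.56 (adjusted p = 0.0778).

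The lung metastasis list, made of genes tied to the LM2 derivatives of MDA-MB-231, had 1 gene that rose (VCAM1) and 1 that fell (IL13RA2, a decoy receptor of interleukin 13, with a log2 difference of -0.58, from 11.21 ± 0.03 to 10.63 ± 0.08) among 21. Adjusted over the list alone 6 rose and 4 fell, and the list did not shift one way (camera adjusted p = 0.638). VCAM1 was also the 1 of 34 integrins and adhesion receptors past the threshold (2 adjusted over the list alone; camera adjusted p = 0.452). TIMP3, an inhibitor of metalloproteases bound to the matrix, rose 1.47-fold from 9.38 ± 0.02 to 9.94 ± 0.12 with all 4 of its probe sets higher, as 1 of 37 metalloproteases and inhibitors (4 rose and 2 fell adjusted over the list alone; camera adjusted p = 0.0754). The mesenchymal and EMT list had 0 of 44 genes past the threshold (13 at an unadjusted p under 0.05), with 4 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.711) and COL6A1 at 0.36 (adjusted p = 0.109). The TGF-beta response list had 0 of 26 (10 at an unadjusted p under 0.05), with 5 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.0635) and PMEPA1 at 0.44 (adjusted p = 0.0733).

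No list of epithelial identity genes was called in the main fit. The epithelial junction list had 0 of 34 genes past the threshold (6 at an unadjusted p under 0.05) and 1 lower adjusted over the list alone (camera adjusted p = 0.711), with the desmosomal gene PKP2 at -0.45 (adjusted p = 0.0951). In the simple epithelial and luminal list KRT7 was the 1 of 25 that fell, with 1 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.731). The basal and squamous list had 0 of 37 past the threshold (5 at an unadjusted p under 0.05) and 2 higher adjusted over the list alone (camera adjusted p = 0.452), with KRT80 at 0.45 (adjusted p = 0.0725). However, it was called as higher with each filter on dim genes (camera adjusted p = 0.0310 and 0.00215). The other KLF and SP factors had 0 of 24 in either adjustment and 2 at an unadjusted p under 0.05 (camera adjusted p = 0.807), with KLF9 at 0.26 (adjusted p = 0.245). In the Notch pathway list DTX3 fell 1.51-fold as 1 of 29 genes (2 adjusted over the list alone; camera adjusted p = 0.711), although its 5 probe sets ranged from -0.59 to 0.24. The WNT target list had 0 of 19 in either adjustment and 3 at an unadjusted p under 0.05 (camera adjusted p = 0.711, DKK1 at -0.26), and the pluripotency and stem cell list had 0 of 19 (2 at an unadjusted p under 0.05), with 1 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.638, SOX4 at -0.32). For the KLF and SP, epithelial junction and Notch lists the mean and median were positive and the camera direction was down. For the simple epithelial list only the median was positive, and for the p53 list only the mean.

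**Figure D3:**
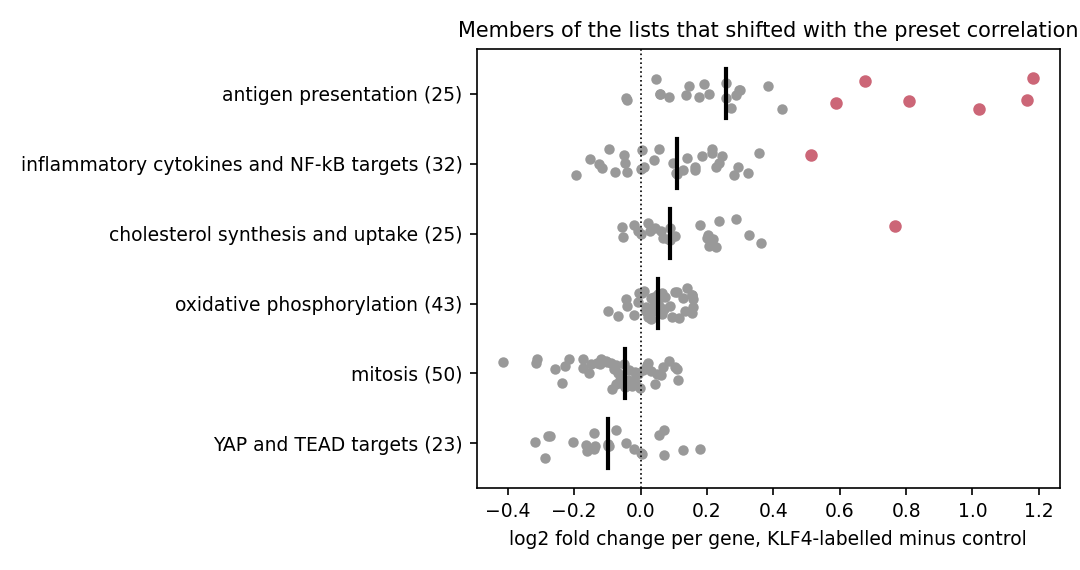
Log2 fold change (KLF4-labelled minus control) of each measured gene in the 6 lists that shifted with the preset correlation, with 1 point per gene, genes past the limma threshold in red, the list median as a black bar and the number of measured genes in brackets. The medians run from 0.26 for antigen presentation to -0.10 for YAP and TEAD targets, and none of the 6 shifts passes with an estimated correlation.

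Markers of other cell types and of RNA quality were compared in the same way. The endothelial marker list had 0 of 18 genes past the threshold (5 at an unadjusted p under 0.05) and 4 higher adjusted over the list alone (camera adjusted p = 0.0754). It was called as higher with the probe set of largest SD (adjusted p = 0.0399) and without control replicate 2 (0.0220). In it TIE1 differed by 0.48 (adjusted p = 0.103) with its 2 probe sets of opposite sign, and its brightest members differed by 0.25 (ROBO4) and -0.02 (ESAM). The fibroblast marker list had 0 of 20 past the threshold (5 at an unadjusted p under 0.05) and 1 lower adjusted over the list alone (camera adjusted p = 0.711), with DCN at -0.40, COL1A1 at -0.45 and FBLN1 at 0.08. The 5 probe sets of FBLN1 ranged from -0.19 to 0.72, with 4 higher and 1 lower. Ribosomal protein genes (0 of 40 in either adjustment and 0 at an unadjusted p under 0.05, camera adjusted p = 0.402, RPL6 at -0.07) and housekeeping genes (0 of 25 in either adjustment and 2 at an unadjusted p under 0.05, camera adjusted p = 0.619, RAB7A at 0.30) were not called. Beside KRT7, DTX3 and TIE1, probe sets of opposite sign were seen for COX4I1, GINS2, COL6A1, KLF9, DCN, COL1A1, FBLN1 and RAB7A, of which the brightest is given. The 3' minus 5' log2 difference of the ACTB control probe sets was 0.04 ± 0.03 in control and 0.03 ± 0.07 on the KLF4-labelled arrays (SD, n = 3 each). For GAPDH it was -0.03 ± 0.03 and -0.04 ± 0.04, so the groups differed by less than the spread between arrays on both measures.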

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

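The gene comparison used only probe sets with 1 gene symbol, and only 1 of them per gene. The probe sets left out of it carry signal too. In a limma fit over all probe sets that are not controls, 5 probe sets with several gene symbols were higher on the KLF4-labelled arrays at an adjusted p under 0.05, by 0.92 to 1.04 on the log2 scale, and 2 were lower. They are not assigned to a gene here. In the same fit 1 probe set unnamed here, 223839_s_at, was higher on the KLF4-labelled arrays, at 6.08 ± 0.04 in control and 6.84 ± 0.15 (SD, n = 3 each; adjusted p = 0.0413), and 1 unnamed probe set, 226482_s_at, was lower, by 2.06-fold.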

How the results depend on the processing

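The count of 76 changed genes depends on how the spread is estimated and on the number of arrays. It was 326 with a mean log2 value of at least 5 and 445 for the upper part by mean level, where fewer genes are tested, 489 with a robust, level-dependent prior, 131 with array weights, 30 with the probe set of largest SD, 22 without probe sets marked _x_at or _s_at and 0 with an ordinary t statistic (2329 at an unadjusted p under 0.05); apart from the fewer genes tested, the cause was not tested. Leaving out 1 array gave 13 to 26 genes, with fewer samples in the fit, 5 to 7 genes at least 2-fold changed, 56.2% to 80.8% higher, KLF4 at -0.41 to -0.32 and 5 to 11 lists. The highest share and the 11 lists both came without KLF4-labelled replicate 2. Of the 76 genes, 13 passed in all 6 of these fits and 49 in none. The 6 genes at least 2-fold changed became 3 without _x_at or _s_at probe sets, 0 with an ordinary t statistic and 0 in limma's test against a 1.5-fold change (16 genes at an unadjusted p under 0.05). KLF4 stayed at -0.37 and passed with both filters (adjusted p = 0.0320 and 0.0156) and with the robust prior (0.0118), and it was negative with an adjusted p between 0.0118 and 0.349 in all alternatives that read it; no value exists without _s_at probe sets, since both of its probe sets are so marked. KRT7 turned from -0.80 to 0.048 without _x_at or _s_at probe sets, where another of its probe sets is read. That probe set is dimmer (control level 6.57), and its SE over all probe sets was 0.13, so the value shows no rise. In this setting 59 of the 61 called genes that could be tested kept their direction. The lists called went from 6 to 10 with array weights and to 0 with an estimated correlation, while fry called 4. Lists not called at first passed as higher under these settings: basal and squamous with both filters, interferon with the stricter filter, the mean over probe sets, array weights and the ordinary t statistic, TGF-beta with the last 2 and without _x_at or _s_at probe sets, hypoxia with array weights and the ordinary t statistic, NRF2 with array weights, and endothelial markers with the probe set of largest SD. Without 1 array the new calls were interferon, TGF-beta, hypoxia, NRF2 and DNA replication (KLF4-labelled replicate 2, adjusted p 0.0134 to 0.0184), endothelial markers (control replicate 2, 0.0220) and metalloproteases (control replicate 3, 0.0482). The replicate block gave 9 genes, but same-numbered arrays deviated together in no pair (r = -0.19, -0.07 and -0.06), and no array correlated best with its own number. These values show no pairing by replicate number. Between arrays of different numbers r ran from -0.13 to 0.20. The highest values were 0.20 for control replicate 1 with KLF4-labelled replicate 2, 0.19 for control replicate 3 with KLF4-labelled replicate 1 and 0.08 for control replicate 2 with KLF4-labelled replicate 3. Each array is in 1 of these pairs, so a pairing under other numbers stays open. It was not tested, and the main fit uses no pairing. Over all settings, 595 list results were on the same side of the threshold, 20 passed newly, 22 lost the call and 0 turned, and for named genes these counts were 741, 46, 190 and 1. Without detection calls, the values do not show which dim genes lie above background.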

Other observations

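The medians of the other MAGE and semaphorin genes and the count of splits for the lists were chosen before their results were seen. The tests on KLF4, the class II genes, RAP1A and the laminins, the camera tests of the families, and the splits for the gene counts, were chosen after the result was seen, as were the genes named in the next paragraph.

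Several secreted and inflammatory genes outside the naming rule also rose on the KLF4-labelled arrays (limma adjusted p under 0.05, n = 3 per group). ALOX5AP, which serves leukotriene synthesis, rose 1.57-fold, from 7.72 ± 0.06 to 8.37 ± 0.10, beside the prostaglandin enzyme PTGES. The complement component C3 rose 1.49-fold and CCRL2, a receptor that binds the chemoattractant chemerin, 1.55-fold. The matrix genes CTHRC1 and HTRA1 rose 1.56-fold and 1.39-fold, and the growth factor PTN rose 1.34-fold. Among the falls were the guidance ligands SEMA3E (at a dim level, 4.31 ± 0.11 to 3.70 ± 0.13) and SEMA3A (1.42-fold lower). None of these is in a list fixed before the data were examined, so no theme is claimed for them.

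Whether the families of some called genes fell as a group stays open, because a median of the other members leaves out the genes that were called. The bound above -0.1 set for that median was wrong as a test for this reason, and it excludes no family. Of the 5 MAGEA, MAGEB and MAGEC genes with a mean log2 level of at least 5, 3 fell past the threshold (MAGEB2, MAGEA6 and MAGEC2) and the other 2 had a median of 0.12, with MAGEA12 at 0.24 and MAGEC1 at 0.0043. Over these 5 genes camera gave an unadjusted p of 6.9e-05 (p = 0.015 with an estimated correlation), in a set formed because 3 of its genes had been called. The class 3 semaphorins other than SEMA3A and SEMA3E had a median of -0.0098 (range -0.15 to 0.23, n = 5), and over all 7 the camera p was 0.061 (0.126 with an estimated correlation). The laminin chains other than LAMB1 with a mean log2 level of at least 5 had a median of -0.022 (range -0.22 to 0.24, n = 8), and with LAMB1 the camera p was 0.146 (0.387 with an estimated correlation). In addition 1 probe set of LAMA4, not the one that represents the gene, was lower by 1.60-fold and passed over all probe sets. All the called genes of these families kept their direction under the 3 other scalings.

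KLF4 was lower on the KLF4-labelled arrays. An exchange of 1 array between the groups is argued against by the splits, because the highest count of changed genes in the 9 splits with 1 array of each group exchanged was 0, against 76 as labelled. An exchange of all labels remains open: the difference of -0.37 (95% interval -0.54 to -0.20) has the sign it needs, but the size of the over-expression is not given, and if it were so every rise described here would be a fall. A plasmid-borne KLF4 mRNA that lacks the part these probe sets read is open as well, since the probe table has 0 columns with probe positions, and the endogenous gene could then be lower. A real loss of the over-expression in these cultures was not tested.

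The MHC class II genes rose together. Probe sets that read several HLA genes are argued against for HLA-DPA1, whose further probe set not marked _x_at or _s_at differed by 0.74 (95% interval 0.56 to 0.91). Its mean level of 5.44 lies only a little above the limit of 5 used here for a bright probe set, which weakens the argument. For HLA-DRA, HLA-DMB, HLA-DRB1, HLA-DPB1 and HLA-DMA the same explanation stays open, with 0 bright probe sets not so marked beside those that gave the calls. HLA-DRA and HLA-DMB were called on probe sets that are themselves not so marked (1.18 and 0.68, mean levels 8.49 and 6.54), but a probe set that gave a call cannot test it. HLA-DRB1, HLA-DPB1 and HLA-DMA were called on marked ones. The dim unmarked probe set of HLA-DPB1 (mean level 3.34) differed by 0.10 ± 0.10 (SE), against 1.16 on its marked probe set. Blood cells or their RNA in the KLF4-labelled samples stay open too. The 9 haematopoietic markers with a control mean of at least 5 had a median of 0.14, with LAPTM5 at 0.27 and LCP1 at 0.19. An interval of 0.03 to 0.24 around this median was taken from the SD over the markers, treated as independent. It does not measure the spread between arrays, so it decides nothing here. The 10 dimmer markers, with a median of -0.10 (range -0.21 to 0.16), lie too near the floor to exclude blood cells. All 19 together had a median of 0.0064. A gain of the class II regulator CIITA at the RNA level cannot be told apart from none, since its brightest probe set differed by 0.060 (95% interval -0.08 to 0.20) and its dim ones by 0.44 ± 0.16 and 0.019 ± 0.20 (SE); an effect of KLF4 or of differences between the cultures stays open, untested.

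RAP1A, a small GTPase, was chosen after its values were seen: its probe sets 1555339_at and 1555340_x_at were lower by 3.31-fold and 3.48-fold on the KLF4-labelled arrays, more than any gene in the main comparison. A fall of all RAP1A mRNA is argued against, as the brightest probe set differed by 0.037 (95% interval -0.16 to 0.24). A single deviating array is argued against as well, since without each array in turn the smallest fall on either probe set was -1.56 on the log2 scale. A transcript form or another sequence read by the 2 probe sets is open, and without probe positions it was not tested.

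With 3 arrays against 3 there are 10 splits of the arrays, too few for a share under 0.05. The labelled split gave 76 changed genes and the highest other split 0 (at an unadjusted p under 0.05, 2483 genes and at most 1435), and at least 2-fold changed genes numbered 6 and 0. The labelled split gave 6 shifted lists and the highest other split 4. In each of the 3 results 1 split, the labelled one, gave a result as large.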
